A study of Homo sapiens with 8 samples.

How the data were processed

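The series holds small RNA libraries of exosomes and mRNA libraries of recipient cells, all human. Exosomes, small vesicles released by cells, came from THP-1, a monocytic leukaemia line, per the labels, as M0-exo (1 library) and M2-exo (1 library); M0 and M2 are the usual names for unpolarised and alternatively activated macrophages. Recipient cells were Caco-2, a colorectal carcinoma line that stands for intestinal epithelial cells in the series design, treated with buffer (3 libraries, called untreated here) or with M2-exo (3 libraries). Dose, time of treatment and culture origin of the replicates are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

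The exosome table, as deposited by the authors, holds read counts per miRNA and TPM values for both libraries. Bowtie is named in the submitters' processing notes; its version, the miRNA database and the genome build are not given in the sources used here. The deposited TPM values are each count divided by the column total, on the usual TPM scale (largest difference 4.06e-05), so only the counts were used. The gene table deposited by the authors holds whole-number counts for 58735 genes with Ensembl identifiers, coordinates and types. CASAVA, HISAT2, featureCounts and the build GRCh38 are named in the submitters' processing notes, with versions not given in the sources used here. A matching FPKM table deposited by the authors gives each count divided by gene length and by a constant per column. The strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here, so values of near-identical copies and of antisense or overlapping genes are uncertain. A total of 6 columns in the gene tables match no sample of the series and were not used in any step. Every gene symbol comes from the gene table; the 610 fixed list memberships were all matched to it, 2 of them through an older or newer symbol.

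Caco-2 counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which left 15084 genes, TMM scaling, the quasi-likelihood F test without robust fitting, 2-sided, and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were the size of the change divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD of 3 libraries. The 33 fixed gene lists, each with at least 5 tested members, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and adjusted over the 33 lists. An estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. For the exosome libraries, with 1 per group, no test was possible. Shares of the counts were compared as ratios, with exact conditional binomial 95% intervals for the ratio and exact Clopper-Pearson 95% intervals for each share (scipy 1.17.1). These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. A miRNA was to be counted as higher at a ratio of at least 2 and as lower at a ratio of at most 0.5, among entries with at least 50 counts in the higher library.

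The following choices were made before the data were examined: the tests, the 33 gene lists and 8 miRNA lists, the alternatives and the rule for named genes. For Caco-2, the rule took the 12 largest changes in each direction among genes past the adjusted threshold, with no overlap between the 3 treated and 3 untreated values, a mean CPM of at least 5 and a protein-coding type, and filled empty places with the smallest unadjusted p under the same filters, named as not passing. It added up to 2 higher and 2 lower members of each list; the text names most of the genes that the rule took, not all of them. For exosomes, it took the 10 most abundant miRNAs of each library, the 8 largest and 8 smallest ratios, and list members with at least 50 counts. Alternatives were DESeq2 1.42.0, RLE size factors, total counts, no filter, a mean CPM of at least 1, limma-voom, an added fold threshold, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, and each library left out; for exosomes, TMM or median ratio factors, shares without the most abundant miRNAs, and other minimums and thresholds. A planned search for miRNA seed matches in 3′ untranslated regions was not run because no transcript sequences were given; only the 6 fixed miRNA target lists were tested.

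Caco-2 library totals ranged from 15608937 to 18324599 counts. The median 95% interval of a log2 fold change reached 0.51 to each side. Recovery was checked on 5 simulated tables drawn from the means and spreads of the 15084 tested genes. In each, 200 genes with a mean CPM of at least 5 were changed. There edgeR recovered 7.16% of 1.5-fold, 42.7% of 2-fold and 97.6% of 4-fold changes, and called 46 of 74206 unchanged genes. For lists, camera recovered 10 of 10 shifted by 1.5-fold and called 2 of 155 unshifted. The genes were drawn independently of each other. These list rates therefore do not hold for lists whose genes move together, such as the mitochondrially encoded genes (estimated correlation 0.81). The gene rates belong to such simulated tables with 200 changed genes and need not hold for the real libraries. There edgeR gave 111 genes at an unadjusted p under 0.05, against 754 expected by chance. The ratio intervals for miRNAs covered the true ratio in 96.1% of 1550 simulated cases over 31 entries. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so none is given per gene. No pair of libraries differed by as little as sampling noise: the chi-square per gene was at least 8.87 for each of the 15 pairs.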

Results

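The series asked which miRNAs macrophage exosomes carry and what mRNA changes follow in intestinal epithelial cells given M2-exo. Small RNA of exosomes from THP-1 cells was measured in 1 M0-exo and 1 M2-exo library, with totals of 13584 and 9929 miRNA counts. Whether these small totals are whole libraries is not stated in the sources used here, so every share, ratio and limit below describes the deposited counts only. The mRNA of Caco-2 cells was measured in 3 untreated libraries and in 3 M2-exo treated libraries. The untreated totals were 15608937, 17462784 and 18324599 counts, and the treated totals 17408745, 17730203 and 18184325.

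The first comparison set the miRNA content of M2-exo beside that of M0-exo. In both libraries miR-21-5p, a member of the fixed list of myeloid miRNAs, was the leading miRNA. It held 27.2% of counts in M0-exo (95% exact interval 26.4 to 27.9) and 19.5% in M2-exo (18.7 to 20.3), a ratio of 0.718 (0.679 to 0.759). The next in M0-exo, miR-148a-3p, held 12.5% there and 13.7% in M2-exo. Larger shares in M2-exo were held by miR-30c-5p, at 4.87% in M0-exo and 6.92% in M2-exo (ratio 1.42, 1.28 to 1.58), by miR-92a-3p (ratio 1.38, 1.19 to 1.60) and by miR-143-3p (ratio 1.45, 1.24 to 1.70). Another was miR-155-5p, a miRNA induced by inflammatory signals, at 1.88% and 2.59% (ratio 1.38, 1.15 to 1.65). Beside miR-21-5p, a smaller share in M2-exo was held by miR-151a-3p, at 6.07% and 4.02% (ratio 0.662, 0.586 to 0.747). The 10 most abundant miRNAs held 70.7% of M0-exo and 67.1% of M2-exo counts and had 9 members in common. With 1 library each, these values compare 2 libraries, not 2 conditions, and have no replicate check.

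None of the 31 miRNAs with at least 50 counts had a ratio of at least 2 or at most 0.5. The largest ratios were 1.71 for miR-26a-5p (1.37 to 2.15), 1.64 for miR-222-3p (1.19 to 2.26), 1.63 for miR-320a-3p, 1.62 for miR-425-5p, 1.55 for miR-486-5p and 1.52 for miR-451a, followed by miR-486-3p with 0.611% and 0.917% of counts. The smallest were 0.604 for miR-30e-3p (0.391 to 0.916), 0.662 for miR-151a-3p, 0.671 for miR-146a-5p (0.470 to 0.947), 0.705 for miR-221-3p, 0.718 for miR-21-5p, 0.771 for miR-146b-5p and 0.831 for let-7g-5p, followed by miR-100-5p with 0.986% and 0.937%. Thus miR-221-3p and miR-222-3p, which come from the same gene cluster, lay on opposite sides of 1. Of the 31, 20 had a ratio above 1, with an interval that excluded 1 in 14, and 11 a ratio below 1, with such an interval in 6. They include 2 pairs with equal counts, miR-3184-3p with miR-423-5p and miR-3529-3p with miR-7-5p, so 29 entries had distinct counts, 19 above 1 and 10 below. Nearly equal were miR-486-5p, at 84 and 95 counts, and miR-486-3p, at 83 and 91, which may not be separate observations. The lower share of miR-21-5p, by 7.66 percent points, raises the other shares as a whole. TMM factors, taken from the middle of the ratios and not from miR-21-5p alone, divide each ratio by 1.26 (log2 0.33). They leave 16 ratios above 1 and 15 below, and turn the balance of intervals that exclude 1 to 2 above and 12 below. They put miR-148a-3p at 0.864, let-7f-5p at 0.829, let-7a-5p at 0.852 and miR-21-5p at 0.570.

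**Figure D1:**
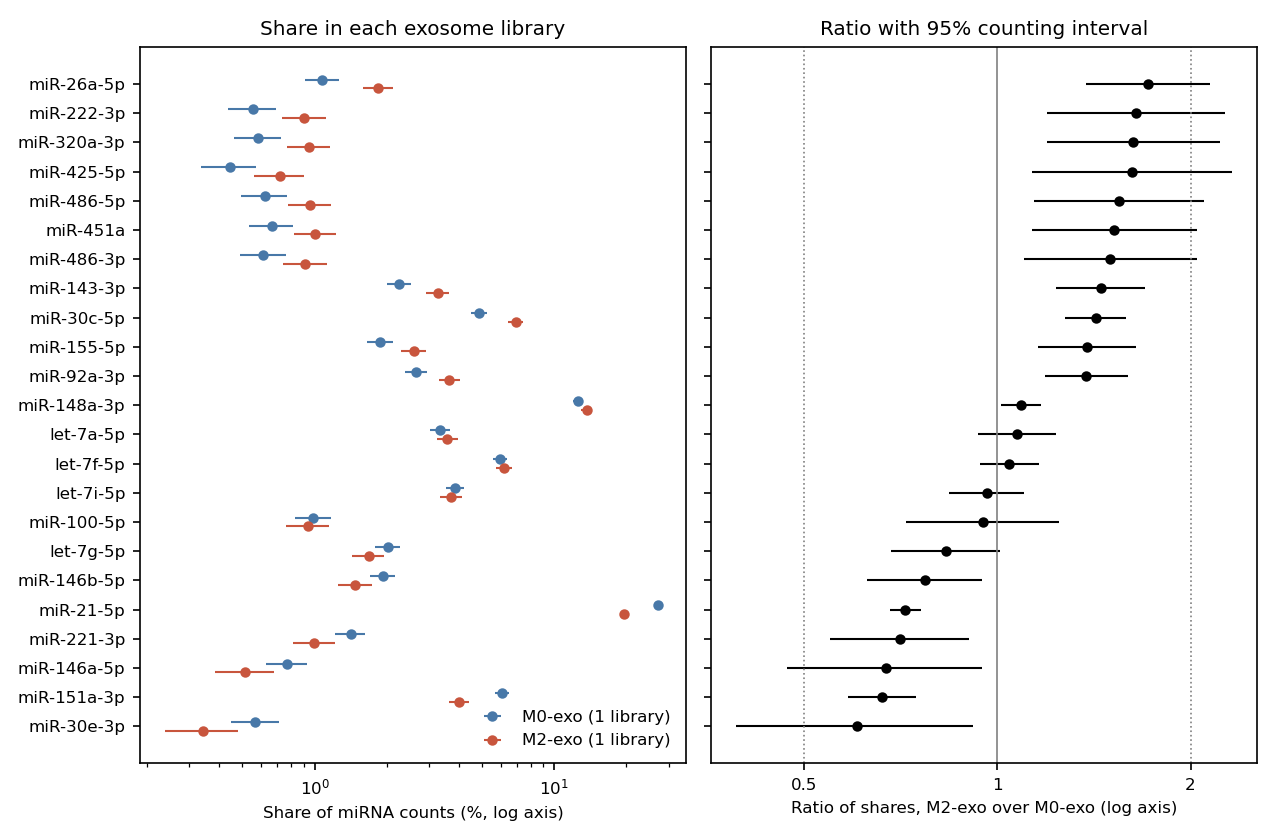
The left plot gives the share of miRNA counts (percent, log axis) in the M0-exo and M2-exo library for the miRNAs named by rule, with exact 95% intervals, and the right plot the ratio of shares with its 95% counting interval. Ratios lay between 0.604 for miR-30e-3p and 1.71 for miR-26a-5p, inside the dotted lines at 0.5 and 2.

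By fixed list, the let-7 family held 16.3% of counts in each library (ratio 1.00, 0.938 to 1.07; 0.794 with TMM factors). The 12 listed myeloid miRNAs, mostly miR-21-5p, held 32.4% of M0-exo and 24.6% of M2-exo counts (ratio 0.758, 0.721 to 0.796, and 0.602 with TMM factors). The 11 others without miR-21-5p held 5.28% and 5.08% (ratio 0.962, 0.856 to 1.08, and 0.763 with TMM factors). Among these, miR-146b-5p held 261 and 147 counts and miR-155-5p 255 and 257. By contrast, miR-142-3p held 2 and 0, miR-142-5p 5 and 1, and miR-223-3p 2 and 0. The miRNAs often linked to M2 macrophages gave a ratio of 0.892 (0.763 to 1.04; 0.708 with TMM factors), with miR-222-3p above 1 and miR-221-3p and miR-146a-5p below. Those often linked to M1 macrophages, mostly miR-155-5p, gave 1.33 (1.15 to 1.53; 1.05 with TMM factors). The fixed list of miR-17 and its related gene clusters, which mixes several seeds and is mostly miR-92a-3p, gave 1.32 (1.15 to 1.52; 1.05 with TMM factors). Its members with the miR-17 seed itself held only 30 and 12 counts. Blood and serum miRNAs, led by miR-451a and miR-486-5p of red blood cells, held 1.58% and 2.30% (ratio 1.45, 1.20 to 1.76; 1.15 with TMM factors). Epithelial miRNAs held 50 and 67 counts (ratio 1.83, 1.25 to 2.70, and 1.46 with TMM factors). Muscle miRNAs held 28 and 20 (ratio 0.977, 0.522 to 1.80, and 0.776 with TMM factors). With TMM factors, the intervals of the let-7 family (0.744 to 0.847) and the M2-linked miRNAs (0.606 to 0.827) came to exclude 1. Those of the M1-linked (0.914 to 1.21), miR-17 (0.914 to 1.21), blood and serum (0.952 to 1.39) and epithelial miRNAs (0.994 to 2.14) no longer did.

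The second comparison asked which Caco-2 mRNAs differed after M2-exo. No gene passed the adjusted threshold: edgeR called 0 genes higher and 0 lower among 15084 tested (smallest adjusted p = 0.9999), and so did DESeq2 and limma-voom. The genes of smallest unadjusted p with higher values in all 3 treated libraries included C3, the central complement component, at 93.1 ± 3.88 CPM in untreated and 125 ± 5.25 in treated cells (SD, n = 3 each), a log2 fold change of 0.43 (SE 0.13). The stress-response gene IER3 stood at 21.0 ± 1.17 and 32.9 ± 7.70 CPM (log2 0.65, SE 0.20), and the NF-κB regulator NFKBIZ at 27.6 ± 2.81 and 40.6 ± 8.84 CPM (log2 0.56, SE 0.20). On the other side were AKR1C1, an aldo-keto reductase, at 89.5 ± 10.1 and 55.7 ± 14.2 CPM (log2 -0.68, SE 0.20), and UQCC2, an assembly factor of respiratory complex III, at 43.2 ± 6.62 and 28.7 ± 3.86 CPM (log2 -0.59, SE 0.18). The calcium-binding protein gene S100A4 stood at 39.4 ± 3.03 and 26.8 ± 4.75 CPM (log2 -0.56, SE 0.18). The adjusted p of each of these genes was 0.9999 by edgeR, so none passed once adjusted over all genes tested.

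The remaining genes with higher treated values, none of which passed, were the collagenase gene MMP1 (log2 0.57, SE 0.23), ID1 (0.41, SE 0.16), ZNF30 (0.52) and CMTM7 (0.38). They also held the immediate early gene FOS (0.56), the homeobox gene HHEX (0.44), the Wnt effector LEF1 (0.38), the growth factor gene BMP2 (0.38) and ARRDC3 (0.39). Those with lower treated values, also not passing, included the complex I subunit gene NDUFA2 (-0.45, SE 0.16) and ICA1 (-0.54). Others were ZNF394 (-0.49), FRY (-0.58), the kinase gene RPS6KA5 (-0.58), CHI3L1 (-0.40), the carboxypeptidase gene CPA6 (-0.59) and DTD1 (-0.44). In the GRCh38 coordinates of the gene table, C3 (ENSG00000125730) lies on chromosome 19 from 6677704 to 6730562 and IER3 (ENSG00000137331) on chromosome 6 from 30743199 to 30744554. AKR1C1 (ENSG00000187134) lies on chromosome 10 from 4963253 to 4983283, UQCC2 (ENSG00000137288) on chromosome 6 from 33694293 to 33711727 and S100A4 (ENSG00000196154) on chromosome 1 from 153543613 to 153550136. AKR1C1 has close relatives in the same gene family, between which the counting could split reads.

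**Figure D2:**
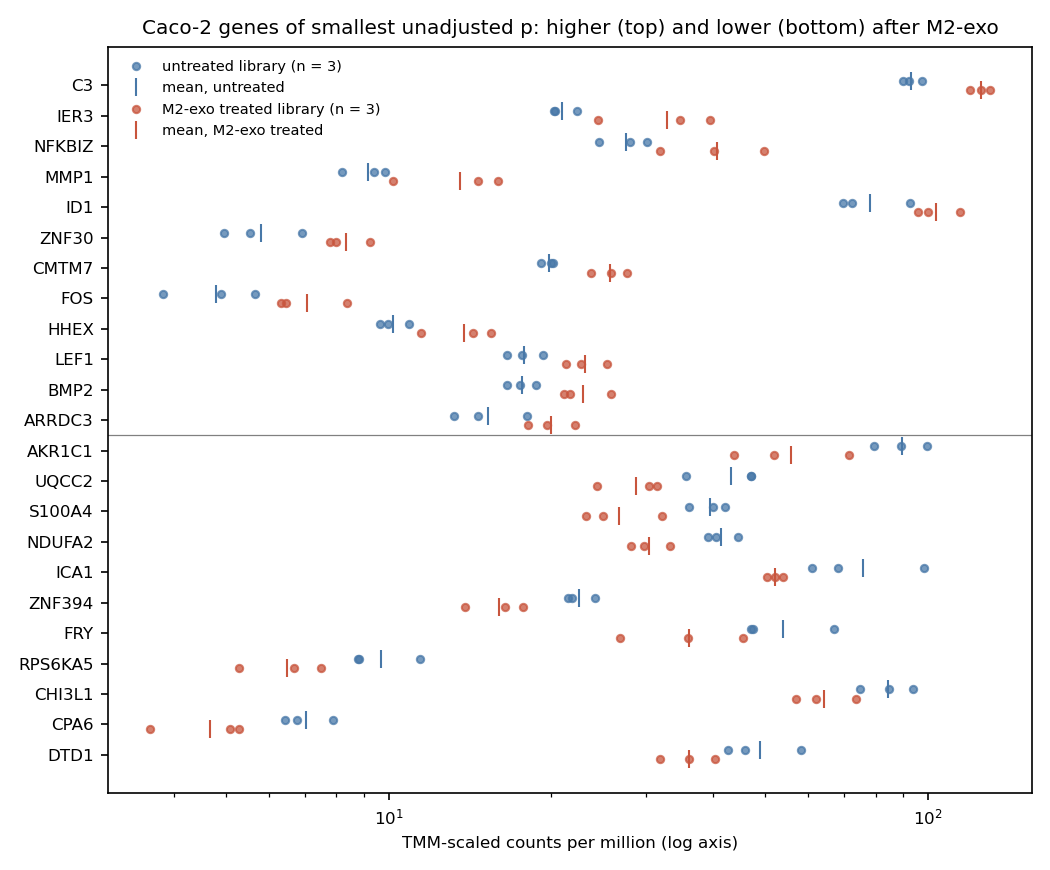
TMM-scaled CPM (log axis) of 23 of the 24 Caco-2 genes taken by rule, with each point a library (3 untreated, 3 M2-exo treated) and each bar a group mean. The upper 12 genes, led by C3, had higher and the lower 11, led by AKR1C1, lower values in all 3 treated libraries, and none passed the adjusted threshold.

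An unadjusted p under 0.05 was reached by 124 of the 29413 genes that DESeq2 tested. It was reached by 111 genes in edgeR and 104 in limma-voom, against 754 expected by chance among the 15084 tested by each. In edgeR this number was 370 without untreated 1 and 349 without untreated 3. Groups did not overlap in 249 genes that were higher and 347 that were lower after M2-exo, together 3.95% of genes, where chance gives 10%. The median size of a log2 fold change was 0.10, and the 95% interval excluded a 2-fold change in either direction for 75.8% of genes and for 94.7% of those with a mean CPM of at least 5. The untreated libraries varied more than the treated ones: the median SD of log2 CPM was 0.30 in untreated and 0.19 in treated cells, and 72.0% of genes were more variable in untreated cells. The first principal component held 50.1% of the variance and did not separate the groups. Its scores were -56.0, 0.479 and 43.2 in untreated 1 to 3, and -13.4, 1.89 and 23.8 in treated 1 to 3. Untreated 1 and untreated 3 thus lay at its ends, and the replicate numbers had the same order in both groups. Genes on the mitochondrial chromosome took 4.16% of counts in untreated 1, 7.48% in untreated 2 and 7.01% in untreated 3, against 7.50%, 7.49% and 8.11% in the treated libraries. Leaving out treated 2 gave 1 higher gene, BOLA2B, named after its values were seen (log2 5.00, edgeR adjusted p = 0.00625). Treated 2 was the treated library without high BOLA2B, at 0.459 CPM against 15.1 in treated 1 and 16.2 in treated 3.

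**Figure D3:**
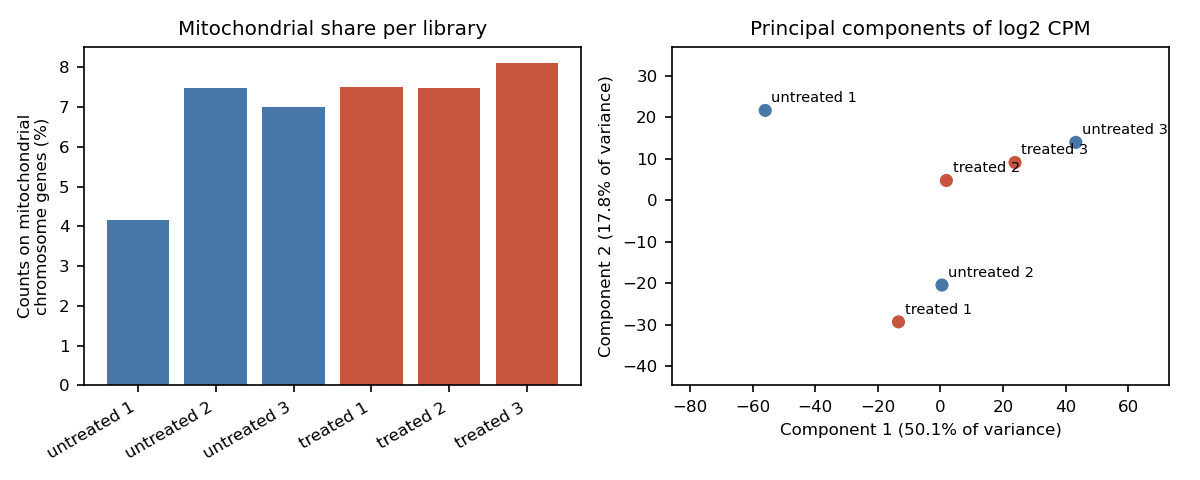
The left plot gives the share of counts on mitochondrial chromosome genes (percent) in each of the 6 Caco-2 libraries, 4.16% in untreated 1 and 7.01% to 8.11% in the others. The right plot places the libraries on the first and second principal components of log2 CPM, which held 50.1% and 17.8% of the variance, with untreated 1 and untreated 3 at the ends of the first.

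Of the 33 fixed gene lists, 4 were called by camera with the preset correlation, and none with an estimated correlation or by fry. No member of any list passed, whether adjusted over all genes or adjusted over the list alone. The 13 mitochondrially encoded genes were higher in treated cells in 12 cases, with a median log2 fold change of 0.39 (adjusted p = 1.84e-06; adjusted p = 0.848 with an estimated correlation). MT-ND4 stood at 7610 ± 3279 and 10614.5 ± 372 CPM (log2 0.48) and MT-ND4L at 1704.5 ± 631 and 2360 ± 498 CPM (0.47), while the exception, MT-ATP8, had 9.99 ± 8.30 and 9.27 ± 5.35 CPM (log2 -0.11, but 0.44 by limma-voom). This call rested on untreated 1, the library with the low mitochondrial share: without it the adjusted p was 0.546.

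The TGF-beta and BMP targets were higher in 10 of 11 cases (median log2 0.16; adjusted p = 0.0498; adjusted p = 0.715 with an estimated correlation). Among them were ID1 at 78.2 ± 12.6 and 104 ± 9.78 CPM and KLF10 at 16.2 ± 2.56 and 21.4 ± 6.41 CPM (log2 0.40), and PMEPA1 was the exception (-0.18). Genes of cholesterol synthesis were lower in 20 of 21 cases (median log2 -0.13; adjusted p = 0.0498; adjusted p = 0.715 with an estimated correlation). They included INSIG1, a regulator of the pathway, at 160 ± 20.9 and 127 ± 17.0 CPM (log2 -0.33) and FDFT1, squalene synthase, at 179 ± 34.7 and 146 ± 11.2 CPM (-0.29). The estimated correlation was -0.040 for TGF-beta and BMP targets and -0.0099 for cholesterol synthesis, both below the preset 0.01. Genes moving together therefore do not account for the higher adjusted p of these lists. Before adjustment, camera with the estimated correlation gave p = 0.043 and p = 0.040. Nuclear genes of oxidative phosphorylation were lower in 24 of 33 cases (median log2 -0.07; adjusted p = 0.0498; adjusted p = 0.876 with an estimated correlation), with NDUFA2 (-0.45) and COX5B (-0.31) at the lower end. TGF-beta and BMP targets and cholesterol synthesis lost the call without any 1 of the 6 libraries, with adjusted p from 0.0771 to 0.523 for TGF-beta and BMP targets and from 0.0617 to 0.546 for cholesterol synthesis. Oxidative phosphorylation lost it without untreated 1 (0.825), untreated 3 (0.456), treated 2 (0.0988) or treated 3 (0.458). With the replicate number as a block, the adjusted p of each of these 3 lists was 0.0501.

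**Figure D4:**
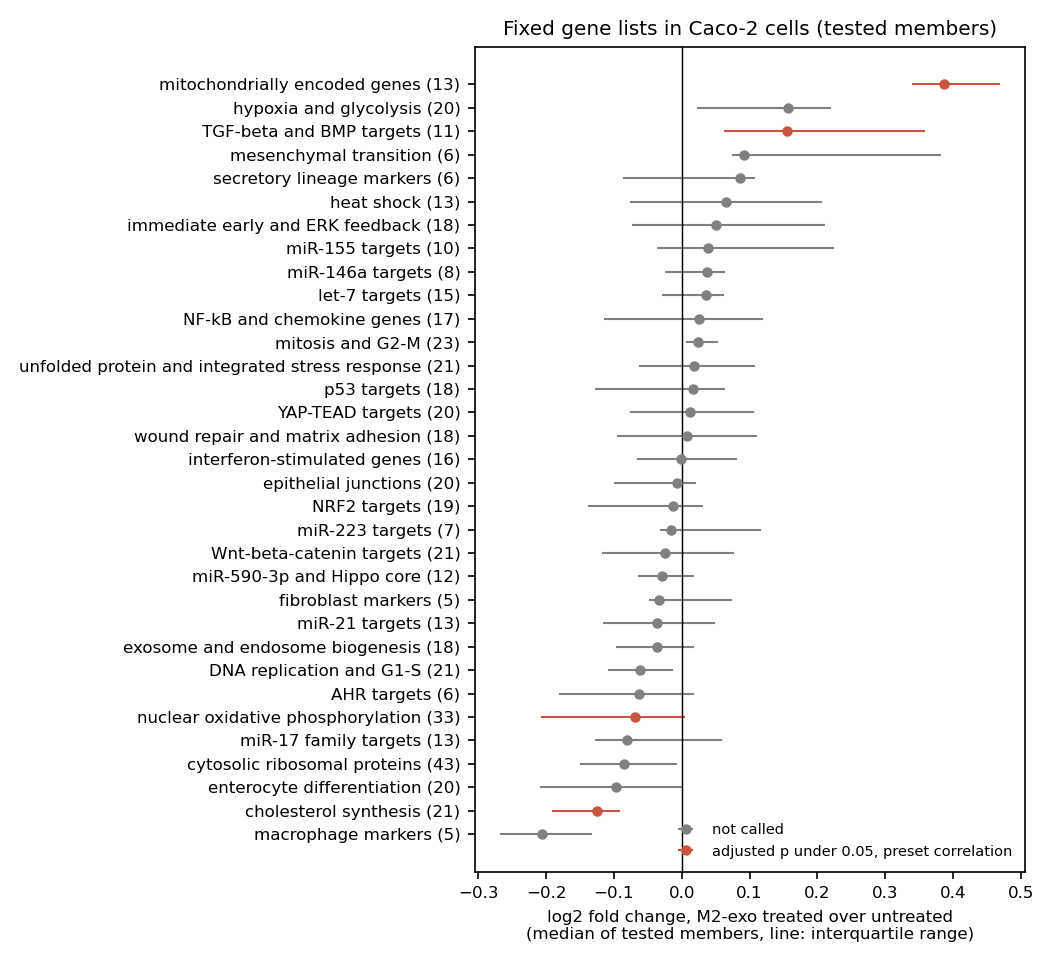
Median log2 fold change, M2-exo treated over untreated, of the tested members of each of the 33 fixed gene lists (number of members in brackets), with the interquartile range as a line. The 4 lists in red had an adjusted p under 0.05 with the preset correlation, from a median of 0.39 for mitochondrially encoded genes to -0.13 for cholesterol synthesis.

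The other 29 lists were not called. Among lists of the cell state, hypoxia and glycolysis genes were above 0 in 16 of 20 cases (median 0.16, adjusted p = 0.0747), with BNIP3 at 0.31, LDHA at 0.22 and VEGFA at -0.25. With a mean CPM of at least 1 they were called (0.0345; there adjusted p = 0.735 with an estimated correlation; 0.0345 to 0.939 over all alternatives). Cytosolic ribosomal protein genes were below 0 in 34 of 43 cases (median -0.08, adjusted p = 0.114), with RPL37 at -0.26 and RPL3 at -0.17. Leaving out untreated 2 brought a call (0.0415; there adjusted p = 0.922 with an estimated correlation), as did leaving out treated 2 (0.0121; there adjusted p = 0.963 with an estimated correlation). All alternatives gave 0.0121 to 0.963. Replication genes were below 0 in 16 of 21 (median -0.06, adjusted p = 0.264), with TYMS at -0.22 and CCNE1 at -0.18, and mitosis genes above 0 in 18 of 23 (median 0.02, adjusted p = 0.632), with CENPE at 0.22. Stress lists gave medians of 0.07 for heat shock (adjusted p = 0.533; HSP90AA1 0.30, HSPE1 -0.42), and 0.02 for the unfolded protein and integrated stress response (0.850; CRELD2 -0.31). Medians were -0.01 for NRF2 targets (0.632; AKR1C1 -0.68, AKR1C2 -0.30, FTL 0.30) and 0.02 for p53 targets (0.861; PLK3 0.45). The mean of the p53 list was below 0, at -0.002, against its median and test. AHR targets had a median of -0.06 (0.938; CYP1B1 0.62, AHRR -0.38, but -1.24 without treated 3).

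Among signalling lists, immediate early and ERK feedback genes had a median of 0.05 (adjusted p = 0.533), with EGR1 at 14.8 ± 8.14 and 30.5 ± 9.13 CPM (log2 1.04, SE 0.41), FOS at 0.56 and DUSP1 at -0.35. NF-κB and chemokine genes had a median of 0.03 and a mean of -0.02 (adjusted p = 0.910, test upward), with IER3 at 0.65, NFKB2 at 0.30 and the chemokine gene CCL20 at -0.58. Interferon-stimulated genes had a median of -0.002 against a mean of 0.02 (adjusted p = 0.861, test upward; IRF7 0.25, ISG15 0.21). YAP-TEAD targets had a median of 0.01 (adjusted p = 0.942; AXL 0.31, CRIM1 -0.34) and Wnt targets -0.02 against a mean of 0.01 (0.910, test upward; LEF1 0.38, MYC 0.38, SMOC2 -0.37). The list of miR-590-3p and the Hippo core had a median of -0.03 (0.853; STK3 -0.28, SAV1 -0.09), and miR-590-3p had no entry in the exosome table.

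Among lists of epithelial identity, enterocyte differentiation genes were below 0 in 15 of 20 cases (median -0.10, adjusted p = 0.632), with FABP1 at 20.7 ± 8.52 and 15.2 ± 2.82 CPM (-0.45), SLC2A2 at -0.51 and SLC2A5 at 0.60. Without untreated 1 the list was called downward (adjusted p = 0.0256; there adjusted p = 0.835 with an estimated correlation; 0.0256 to 0.981 over all alternatives). Epithelial junction genes had a median of -0.01 (adjusted p = 0.817; CGN -0.23, MARVELD3 -0.24), and secretory lineage markers 0.09 with a mean of 0.02 (0.942, test downward against both; AGR2 0.11, TFF3 -0.14). Wound repair genes had a median of 0.01 against a mean of -0.01 (0.910, test upward) and mesenchymal transition genes 0.09 (0.200; VIM 0.97 at under 1 CPM, but 0.12 on log2(FPKM + 1), S100A4 -0.56). Genes of exosome and endosome biogenesis had a median of -0.04 (0.533; CD63 -0.26). Of 22 macrophage markers only 5 had enough counts to test (median -0.21, adjusted p = 0.214), with LYZ at 4.12 ± 0.604 and 2.63 ± 1.25 CPM. Without treated 1 they were called downward (0.0475; there adjusted p = 0.729 with an estimated correlation; 0.0475 to 0.939 over all alternatives). Of 12 fibroblast markers 5 were tested (median -0.03 against a mean of 0.05, adjusted p = 0.736, test upward; PDGFRA 0.37).

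The last comparison asked whether known targets of exosome miRNAs differed in the recipient cells, where added miRNA would predict lower target mRNA. None of the 6 target lists was called. The let-7 targets were above 0 in 10 of 15 cases (median 0.04, adjusted p = 0.624), with THBS1 at 71.9 ± 5.95 and 83.6 ± 6.63 CPM (0.22), HMGA2 at 0.16 and IGF2BP2 at -0.10. The miR-21 targets were below 0 in 7 of 13 (median -0.04, adjusted p = 0.736), with TIMP3 at 276 ± 62.5 and 211 ± 29.1 CPM (-0.39), SATB1 at -0.25 and SPRY1 at 0.24. Medians were 0.04 for miR-155 targets (0.791; SOCS1 0.31) and 0.04 for miR-146a targets (0.850; TRAF6 0.07). They were -0.08 for targets of the miR-17 seed against a mean of 0.0004 (0.980, test upward; TGFBR2 0.23) and -0.02 for miR-223 targets against a mean of 0.04 (0.850, test upward; FOXO1 0.15). The miR-17 list hardly tests the prediction, since carriers of that seed held 12 of the 9929 M2-exo counts. The prediction does not apply to the miR-223 list, since miR-223-3p had 2 counts in M0-exo and 0 in M2-exo, where a count of 0 allows a share of up to 0.0302% (3 counts of the total).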

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

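The leaving out of untreated 1 and untreated 3 together, the covariate, the older edgeR fit, the estimated correlation for lists called only under an alternative, and the miRNA count by interval at any ratio were chosen after the result was seen. Of the 24 Caco-2 genes taken by rule, 0 turned direction and 0 passed under 16 alternatives each (smallest adjusted p 0.954). They were picked for values without overlap between the groups, so leaving out a library could hardly turn their direction. Genes at an unadjusted p under 0.05 by edgeR were 111 with all libraries, 76 to 370 without 1 library and 572 with the covariate. Counts of genes higher and lower were 0 and 0 under every alternative except 2. Without a filter there were 3 higher and 3 lower (29414 genes tested, 493 at an unadjusted p under 0.05), among them EGR1 (log2 1.05) and BOLA2B (4.44); in that fit the prior degrees of freedom were infinite, against 5.25 with the filter, so gene spreads were fully pooled. Leaving out 1 library gave 0 to 1 higher, the 1 being BOLA2B without treated 2 (log2 5.00; 3.99 to 5.00 over the libraries left out; 2.13 on log2(FPKM + 1) with all libraries). With the replicate number as a block in edgeR, no gene passed (211 at an unadjusted p under 0.05, smallest adjusted p 0.415). Deviations of libraries with the same number correlated across genes at 0.28, -0.06 and 0.48. Between untreated and treated libraries of different numbers the correlation lay between -0.42 and 0.18.

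Of the 4 lists called, 0 were called with an estimated correlation, 0 by fry, 1 with the block, 0 to 2 without 1 library (1 to 3 lists of any kind) and 0 without both untreated 1 and untreated 3; the cause was not tested. All 4 were called with RLE size factors and at a mean CPM of at least 1, and 3 with the first component of the within-group residuals as a covariate. Target lists called stayed at 0. Lists called only under an alternative (enterocyte, ribosomal, macrophage, hypoxia) had an adjusted p of 0.729 to 0.963 there with an estimated correlation. The ribosomal list turned upward without both untreated 1 and untreated 3 (adjusted p 0.808); the cause was not tested. MT-ATP8 turned to 0.44 by limma-voom, 0.27 with the block, 0.45 on log2(FPKM + 1) and 0.51 on log2(FPKM + 0.1), and ranged from -0.69 to 0.55 without 1 library; the cause was not tested. Without 1 library, AGR2 ranged from -0.026 to 0.27, TFF3 from -0.42 to 0.089, PMEPA1 from -0.32 to 0.18, SOCS1 from -0.038 to 0.69 and TRAF6 from -0.034 to 0.20; the cause was not tested.

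Counts of miRNAs higher in M2-exo moved from 0 to 4 with a minimum of 25 counts, 6 with a ratio of 1.5 and 14 by interval at any ratio. The 4 include miR-203a-3p and miR-203b-5p, which have equal counts, and 1 entry without a known miRNA name. Those lower moved from 0 to 1 with TMM factors, 1 with median ratio factors, 1 with a minimum of 25 counts, 2 with a ratio of 1.5 and 6 by interval. By interval with TMM factors, 2 were higher and 12 lower. A lower or absent ratio threshold and factors that lower every ratio can add such counts by construction. The minimum of 25 counts only lets in entries of lower count. Among these was miR-320b, with 10 counts in M0-exo and 25 in M2-exo (ratio 3.42, 1.59 to 7.98). The lower entry was miR-27a-3p, with 25 and 5 counts (ratio 0.274, 0.0818 to 0.728). At these totals, 3 counts make a share of 0.0221% in M0-exo and 0.0302% in M2-exo, below which a miRNA could not be told from absent.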

Other observations

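The tests of explanations below were all chosen after the result was seen, as were BOLA2B, the other genes with copies and the genes named by level. In Caco-2 cells, FN1, the gene of the matrix protein fibronectin, was among the most abundant transcripts, at 9279 ± 1063 CPM in untreated and 9789.7 ± 843 in treated cells (SD, n = 3 each), as was the keratin gene KRT8, at 4998.7 ± 1403 and 4892 ± 1063 CPM. A total of 78 miRNA entries had counts in M0-exo only, at most 4 each, and 54 in M2-exo only, at most 3 each, so no miRNA was detectably confined to either library at this depth.

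The higher values of mitochondrially encoded genes after M2-exo may rest on the low mitochondrial share of untreated 1. On log2 CPM the members' median log2 fold change was 0.51 with all libraries and 0.082 without untreated 1, against 0.48 to 0.80 without any other library. The mitochondrial share is made of these same genes, and untreated 1 had the lowest. Leaving it out was therefore bound to lower the median, and only the size of the fall was open. A loss of short transcripts in untreated 1 stays open: the members' median gap between untreated 3 and untreated 1 was 1.46, against a median of 0.13 and a 95th percentile of 1.78 among 71 nuclear genes of like length. Of the 13 members 4 lay above that percentile, and they moved together (estimated correlation 0.81), so they count as few observations. An effect of M2-exo stays open: without untreated 1 the list's adjusted p by camera was 0.546, and 10 of 13 members stayed above 0. The lost call went with the fall of the median, not only with fewer libraries. Leaving out 1 library gave adjusted p by camera down to 8.06e-08. With the 6 libraries split 3 against 3 in the 9 other ways, camera gave this list adjusted p from 1.34e-05 to 0.0970. Several of these were under 0.05, so a call of this list did not need the M2-exo grouping. The real split gave the lowest value, 1.84e-06.

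Untreated 1 and untreated 3 lay farther apart than any other pair of libraries. Whether a difference in depth played a part was not decided: thinning to equal depth left the SD of their log2 gap across 4577 genes at 0.593, against 0.592 before, and with a median counting SD of 0.0504 it could hardly have moved it. Gene length and level are argued against as the whole cause, as 95.4% of the variance of the gap was left after both were removed. Across genes, which are not independent replicates, the gap between untreated 3 and untreated 1 correlated with that between treated 3 and treated 1 (r = 0.53). It correlated less with treated 3 against treated 2 (0.39) or treated 2 against treated 1 (0.24). The gap between treated 3 and treated 1 is the sum of the other treated gaps, so its higher r does not single out the replicate number. A structure shared by libraries of the same number stays open, as does GC content, which could not be tested without sequences, and no biological explanation was tested.

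BOLA2B stood at 0.480 ± 0.181 CPM in untreated and 10.6 ± 8.79 in treated cells (SD, n = 3 each). Reads moved between BOLA2B and its copy BOLA2 are argued against, since the log2 ratio of their sum was 4.36. Reads that match both copies, counted in some libraries only, stay open: the highest treated library was 35.3 times the lowest. An effect of M2-exo cannot be told apart from this, as 2 of the 3 treated libraries lay above all untreated ones. U2AF1L5 and SMIM11A, also called without a filter, have copies too. U2AF1L5 held 1.59, 2.12 and 8.99 CPM in untreated 1 to 3 and 1.63, 16.5 and 17.6 in treated 1 to 3. The log2 ratio of its sum with U2AF1 was 0.22. SMIM11A held 6.09 CPM in untreated 1 and 0.459 to 0.843 in the other libraries. The other genes called there were EGR1, C6orf48 and RN7SL2.

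The 6 Caco-2 libraries can be split in 10 ways, too few for a share under 0.05. The real split called 0 genes by edgeR (111 at an unadjusted p under 0.05) and the highest other 1. It called 4 lists and the highest other 7, and 0 target lists and the highest other 0. Setting untreated 1, untreated 2 and treated 1 against the rest gave 2738 genes at an unadjusted p under 0.05, and untreated 1, treated 1 and treated 2 against the rest gave 2353, against 754 expected by chance, which may reflect a structure of the samples other than the groups. These 2 splits were picked after all were seen, and the other 7 gave 99 to 654.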
